A study of Drosophila melanogaster with 2 samples.

How the data were processed

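The series is a chromatin immunoprecipitation sequencing (ChIP-seq) experiment on whole Drosophila melanogaster embryos 0 to 24 h old, from a strain that carries tramtrack fused to green fluorescent protein, per the labels. Tramtrack (ttk) is a BTB zinc-finger protein known as a transcriptional repressor. The tagged protein was precipitated with an antibody against GFP, although the antibody field of the labels names ttk, and chromatin had been sonicated to a size range of 200 to 800 bp, per the labels. There were 2 libraries in 1 group, labelled biological replicates 1 and 2. A second condition or control libraries were not analysed here, so no comparison between conditions was possible.

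The deposited files are peak lists in dm6 coordinates, the assembly the labels give. The aligner, the peak caller and their versions are not given in the sources used here. The authors gave each peak a signal value, an IDR score and a summit position. IDR is the irreproducible discovery rate, which compares the ranks of peaks in a pair of lists, and the deposited score rises as it falls. The deposited lists also hold −log10 columns of a q value and of the IDR, which chose no peak here. Each replicate had its own ranked list and its own thresholded list, and the whole series had ranked and thresholded lists made from both replicates. Every peak of the thresholded lists had a score of at least 830 and also stood in a ranked list. Some ranked peaks past that score were absent from the thresholded lists, and the deposited listing names a further file, not used here, among the sources of the thresholded lists. The signal is the authors' own value per peak, with a normalization that is not given in the sources used here. It served only to describe, rank or filter peaks within a list. The files give no read counts, so the depth of each library is unknown and no interval that needs it was computed.

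The list called conservative by the authors was the main list, with peaks on the chromosome arms 2L, 2R, 3L, 3R, 4, X and Y. In the ranked list made from the 2 replicates, a pair of columns gives the signal of the matching peak in each replicate, and these were used for the correlation without being assigned to replicate 1 or 2. To give a named peak's signal in each replicate, the peak with the nearest summit within 150 bp was taken from that replicate's own ranked list. Genes and transcription start sites (TSSs) came from the Ensembl annotation and bases from the NCBI sequence of the same assembly; transposable elements were left out of the gene annotation. Coordinates are given 1-based.

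Overlap of the replicates was counted at a minimum of 1 bp and compared with 1000 random placements of the second list on the same chromosomes, with a one-sided permutation p. Signal correlation used 100000 permutations, two-sided. Summits were annotated in the order promoter (within 500 bp of a TSS), 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic, and compared with 1000 sets of random positions on the same chromosomes with assembly gaps left out. Peak numbers per arm were tested by an exact binomial test against assembled length, with exact Poisson intervals. Of 21 gene lists, promoter-bound members (a summit within 500 bp of any TSS) were tested by Fisher's exact test against all other protein-coding genes, and locus-bound members (a summit in the gene or within 2 kb) against 10000 random lists matched on locus length in 20 bins. Of 16 sequence motifs, matches on either strand within 100 bp of the summit were compared with a window of the same width centred 500 bp to one side, chosen at random, by an exact McNemar test. The same test was run over 2080 6-mers, each taken with its reverse complement. The relation of motif presence to signal was tested with 100000 permutations over peaks, and summits within 500 bp of the 290 annotated tRNA genes were compared with the random positions. All tests but the overlap were two-sided, and p-values were adjusted by Benjamini-Hochberg within each family. Peaks are not replicates: these p-values describe the positions in this pair of libraries.

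The lists, motifs, tests and the rule for named genes were fixed before the data were examined; 7 gene symbols were matched through synonyms afterwards. The rule named the protein-coding gene with the nearest TSS for the 25 peaks of highest signal with overlapping peaks counted once, up to 4 members of each list with the strongest summit, and 16 genes whatever their values. Alternatives were the larger thresholded list, the stronger part of the conservative list, each replicate's own list in place of both, other windows, overlaps and backgrounds, shuffled control sequence, and alternatives chosen after seeing the data. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Each test but the signal correlation was first tried on simulated data. For the gene-list tests these were genes marked as bound independently of each other, without summits shared by neighbours. In the locus test the simulated binding rose by the same length bins that the test matches on. Clustered gene lists were not simulated. With 3815 simulated peaks and an expected promoter share of 40.8%, the annotation test recovered 40.7%; a 6-mer added to simulated windows to give a difference of 9.72 percentage points was recovered at 9.52 points; of 200 random gene lists, 3.5% passed an unadjusted p of 0.05 in the promoter test; and of 200 lists of long genes with simulated binding that rose with length, 4.0% passed in the locus test. Of 20 sets of random peaks, 10% passed the tRNA test.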

Results

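Binding of GFP-tagged tramtrack was mapped by ChIP-seq in whole Drosophila embryos 0 to 24 h old, in 1 group of 2 biological replicates. The question the design addresses is where in the genome this repressor is bound, and how far the replicates agree. Replicate 1 had 3203 peaks in its own thresholded list and 91874 in its ranked list, and replicate 2 had 3075 and 116688. The authors' conservative list over both replicates held 3827 peaks, of which 3815 lay on the chromosome arms (3633 with overlapping peaks counted once), and their larger list held 4745. Read depth is unknown, because the files give peaks and no counts. In what follows, signal means the authors' value for a peak in the conservative list, and the replicate signals come from each replicate's own list.

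The strongest sites of the conservative list had similar signals in both replicates. The peak at the promoter of Ugalt, a UDP-galactose transporter gene (X:2703715-2704054), had a signal of 1161 in replicate 1 and 1126 in replicate 2. At CG14100 (3L:19590459-19590771) the signals were 901 and 1152, and at mRpL41, a mitochondrial ribosomal protein gene (2R:15217593-15217903), 962 and 968. Among the 25 strongest peaks the log2 ratio of replicate 1 to replicate 2 ran from -0.69 at Atat to 0.37 at Fkbp14. Of the 3201 peaks of replicate 1 on the arms, 2182 (68.2%) overlapped a peak of replicate 2, against 1.20% ± 0.196 (SD of 1000 random placements; one-sided permutation p = 0.001, the smallest these can give). In the other direction 70.8% of 2976 peaks overlapped. Across the 3815 conservative peaks the paired signals had a Spearman rho of 0.749 and a Pearson r of 0.849 on the log2 scale (permutation p = 1e-05 each, the smallest these can give), with peaks that had been selected by both signals. Over all 126870 ranked peaks rho was 0.260 and r was 0.354. A peak in both replicates' own ranked lists was found for 3579 conservative peaks, with a median log2 ratio of 0.15 ± 0.49 (SD across peaks), and 4.19% of them lay beyond a 2-fold distance from that median.

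**Figure D1:**
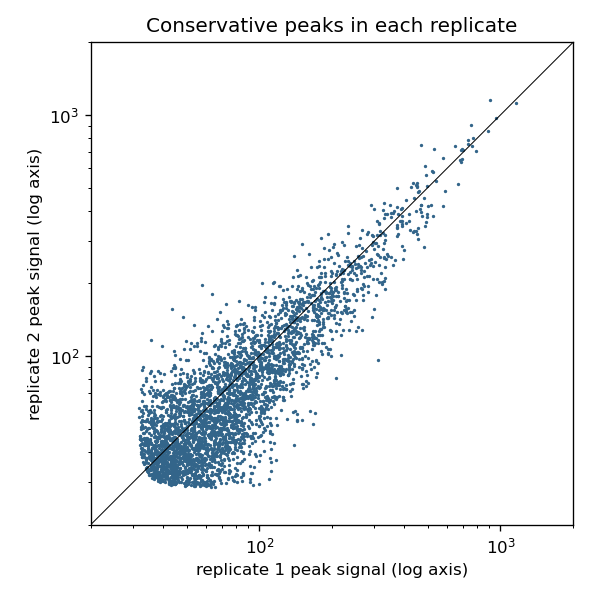
Peak signal in replicate 1 (x axis, log scale) against replicate 2 (y axis, log scale), each point 1 of the 3579 conservative peaks with a peak in both replicates' own ranked lists; the line marks equal signal. Points lie on both sides of the line, and Ugalt, with 1161 and 1126, lies at the upper right.

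Tramtrack-GFP summits lay mainly at promoters and in introns, and were nearly absent from coding sequence. Promoters held 1662 of the 3815 summits (43.6%), against 13.6% ± 0.521 of random positions (SD of 1000 sets), a ratio of 3.21. Coding exons held 22 summits (0.577% against 13.7%), 3' UTRs held 30 (0.786% against 4.44%), and intergenic sequence 574 (15% against 27.1%). Each of these 4 classes had a permutation p of 0.002, the smallest these sets can give (adjusted p = 0.0035). Introns held 1467 summits, 38.5% against 39.5% of random positions (adjusted permutation p = 0.188), and 5' UTRs and other exons did not pass either (adjusted p = 0.101 and 0.117). With promoters of 250 bp the ratio for introns was 1.05, and with 1000 bp it was 0.860 (adjusted permutation p = 0.0320 and 0.00233, in a range of 0.00233 to 0.833 over the alternatives). With the peaks of replicate 2 alone, introns and 5' UTRs were both lower than random, at ratios of 0.894 and 0.430 (adjusted permutation p = 0.00280 and 0.00466). The deficit in 5' UTRs also passed with the larger list of peaks (ratio 0.602), the stronger part of the conservative list (0.460), both other promoter widths and whole peaks, with an adjusted permutation p of 0.00233 to 0.244 over the alternatives.

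**Figure D2:**
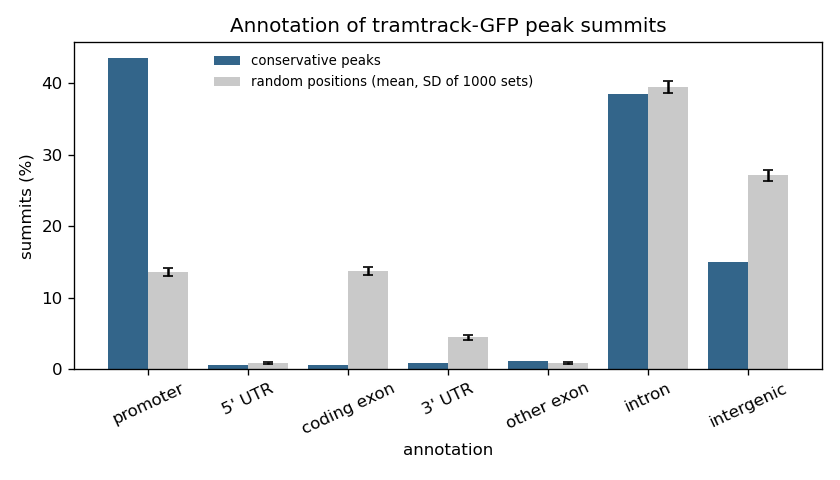
Share of summits (y axis, percent) in each annotation class (x axis) for the 3815 conservative peaks and for random positions on the same chromosomes, with bars for the mean and error bars for the SD of 1000 random sets. Promoters hold 43.6% of summits against 13.6%, and coding exons 0.577% against 13.7%.

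Promoter summits sat just upstream of genes. Of the 1567 promoter summits within 500 bp of a protein-coding TSS, 1282 lay upstream of the nearest one (81.8%, exact 95% interval 79.8 to 83.7%), at a median distance of 128 bp. Of the 25 strongest peaks, 20 had promoter summits. They included, with positions relative to the TSS, Ugalt (-36 bp), mRpL41 (-143 bp), mRpS10, another mitochondrial ribosomal protein gene (-128 bp), PNPase, encoding polynucleotide phosphorylase (-85 bp), and the translation initiation factor gene eIF6 (-102 bp). The Polycomb group gene ph-p had a summit at -493 bp (X:2137177-2137507), with a signal of 1521 (736 in replicate 1 and 788 in replicate 2). Others were nearest to Tcs5, CG7601, px, CenG1A, CG5611, Chro, CG18549, mRpL23, tank, CG8320 and CG9147. Away from promoters, the strongest summits of the conservative list, which leaves out summits in introns of cbt (1986) and Lk6 (1442), were 1033 bp into CG11050 (signal 1762), in introns nearest to Adf1 and CG32772, and between genes at -3165 bp from tara and 11913 bp from CG13323. Among the peaks with signals of at least 227, the highest of 5 equal groups, 58.2% were at promoters, against 38.4% in the lowest of the groups.

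Chromosome X carried more summits per length than the arms together, and chromosomes 4 and Y almost none. X had 767 summits, 32.7 per Mb (exact 95% Poisson interval 30.4 to 35.1), 1.17 times the number expected from its length (adjusted p = 4.22e-06). Chromosome 4, the small and largely heterochromatic dot chromosome, had 1 summit where 37.1 were expected (adjusted exact p = 1.72e-14), and Y had 0 where 94.9 were expected (adjusted p = 2.07e-41). These expectations come from the assembled length of all arms, so the shortage on 4 and Y slightly raises the ratios of X and the other arms. By TSS number the expectations were 29.5 on chromosome 4 and 18.2 on Y. How much of each arm reads can be placed on, and its copy number in the embryos, were not measured. A lack of peaks on an arm therefore need not be a lack of binding. The arms 2L, 2R, 3L and 3R had between 26.5 and 29.6 summits per Mb and did not pass the test (adjusted exact p = 0.09 to 0.234). With the peaks of replicate 1 alone the ratio of X was 1.05 (adjusted exact p = 0.270, the highest over the alternatives, which ranged from 1.69e-08), and 3L passed at a ratio of 1.09 (adjusted p = 0.0309). Chromosome 4 held 12 peaks of replicate 1 and 1 of replicate 2 in their own thresholded lists, and Y held 0 and 5.

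Genes for cytoplasmic ribosomal proteins stood out at promoters, while chemoreceptor and cuticle genes had almost no promoter summits. A promoter summit was found at 1984 of 13968 protein-coding genes (14.2%). Of the 86 ribosomal protein genes, 52 had one (60.5%, against 13.9% of all other genes; adjusted exact p = 6.93e-22), the strongest at RpS27 (signal 513; 204 in replicate 1 and 292 in replicate 2), RpL7 (451), RpL34b (433) and RpL23A (393). None of the 119 odorant and gustatory receptor genes had a promoter summit (adjusted exact p = 1.81e-07), and 1 of the 117 cuticle protein genes did, Cpr65Ea (adjusted p = 4.84e-06). Counting members within 10 kb of each other once ended the call for cuticle genes (2.17%, adjusted exact p = 0.130, in a range of 2.83e-07 to 0.130 over the alternatives). The genes compared were not matched on expression or on how open their promoters are. With no control library used here, these shares cannot separate binding from signal at open promoters that is not specific to the tagged protein. Among genes of BTB-domain transcription factors, the family of ttk itself, 6 of 15 were promoter-bound (40.0%; unadjusted exact p = 0.0129, adjusted p = 0.0679), with Cp190 (467), Trl (244), ttk (197) and lola (97.3) the strongest. This list passed with the larger list of peaks and with promoters of 1000 bp (46.7% each; adjusted exact p = 0.0278 and 0.0376, in a range of 0.0278 to 0.918 over the alternatives). The lola summit had no matching peak of replicate 2.

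The other 17 lists did not pass the promoter test. Corepressor and Polycomb group genes had 6 of 18 members bound (33.3%, adjusted exact p = 0.138), among them ph-p, gro (486), E(z) (424) and MEP-1 (201), and with the peaks of replicate 2 alone the list passed (44.4%, adjusted p = 0.00442, in a range of 0.00442 to 0.788 over the alternatives). The Notch pathway list had 7 of 28 members bound, led by gro, numb (353), E(spl)m2-BFM (167) and E(spl)m3-HLH (152). Tracheal and epithelial junction genes had 9 of 36, with Gli (237), dlg1 (210), dysf (145) and trh (126), and cell cycle genes 7 of 37, with Dp (316), RnrS (305), CycE (185) and BubR1 (148). Muscle structural genes had 4 of 16, with Msp300 (368) and sls (246). EGF receptor and Ras pathway genes had 4 of 25, with spi (236) and aos (232), and proteasome genes 5 of 32, with Rpn3 (136). For segmentation genes 4 of 32 were bound, namely bcd (179), odd (131), cad (109) and run (105), and for Hox genes 1 of 8, Dfd (93.4). Proneural and neural precursor genes had 3 of 31 (numb, neur and insc), neuronal genes 3 of 31 (elav, Fas2 and comt), glial genes 2 of 14 (moody and Gli), dorsoventral and mesoderm genes 3 of 27 (tin, tup and so), ecdysone genes 3 of 21 (E23, Eip75B and usp), eye genes 2 of 19 (ro and so), hemocyte genes 1 of 16 (ush) and fat body and gut genes 0 of 17. The lowest adjusted exact p among these lists was 0.138. The ush summit had a signal of only 2.65, near the lowest of the conservative list (2.10), and no matching peak of replicate 2.

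With the whole gene and 2 kb on each side counted, every BTB-domain transcription factor gene in the list was bound. All 15 of them had a summit, against 51.3% of random genes of like length (permutation p = 0.0002, the smallest these lists can give; adjusted p = 0.00105). The strongest were in an intron of Trl, which encodes the GAGA factor (3L:14759360-14759659; signal 844, with 489 in replicate 1 and 361 in replicate 2), at the promoter of Cp190 (467), at mod(mdg4) (363, at the promoter of the neighbouring gene tin) and in an intron of rib (215). Ribosomal protein genes had 60 of 86 loci bound (69.8%) against 21.5% (adjusted permutation p = 0.00105), and Notch pathway genes 15 of 28 against 30.5% (adjusted p = 0.0412), with summits at gro and the adjoining E(spl)m8-HLH (486), mam (383) and N (372). Chemoreceptor genes (9 of 119, against 24.0%) and cuticle genes (6 of 117, against 20.2%) were bound less often than genes of like length (adjusted permutation p = 0.00105 each). The random lists were matched on length, and not on clustering of members, their expression or how open their promoters are. Members within 10 kb of each other were counted once only in the promoter test. The locus p-values therefore take neighbouring genes as independent and may be too low for clustered lists. The Notch call was lost with the peaks of replicate 1 alone (39.3%, adjusted permutation p = 0.469), in the stronger part of the conservative list (39.3%, 0.0790), with the ranked peaks past its score that this list leaves out restored (53.6%, 0.0554), without flanks (21.4%, 0.612) and with flanks of 5 kb (64.3%, 0.0638), in a range of 0.0162 to 0.612 over the alternatives. Without flanks both low calls were lost too, at 0% against 3.06% and 3.32% of random genes of like length (adjusted permutation p = 0.180 each, the highest over the alternatives, which started at 0.00105).

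The remaining 16 lists did not pass the locus test. Differentiated neuron genes were bound at 9 of 31 loci against 49.3% expected from their length (permutation p = 0.0284, adjusted p = 0.0994), the strongest at elav (527) and Syn (234); with the larger list of peaks this list passed (adjusted p = 0.0162, in a range of 0.0162 to 0.690). EGF receptor and Ras pathway genes were bound at 16 of 25 loci against 42.3% (permutation p = 0.0418, adjusted p = 0.125), with Raf (747), aos (539), S (482) and aop (321); without flanks this list passed (60%, adjusted p = 0.00280, in a range of 0.00280 to 0.701). Strong summits in other lists lay in introns of Hr3 (950) and Hr4 (497), both nuclear receptor genes of the ecdysone response, in the 5' UTR of baz (889), near CycB (708), in norpA (697), at moody (548), at Pc (541), in brat (525) and at Mef2 (585, at the promoter of the neighbouring gene Pal1). Bound loci numbered 7 of 32 for segmentation genes, 3 of 8 for Hox genes, 8 of 31 for neural precursor genes, 7 of 14 for glial genes, 16 of 37 for cell cycle genes (59.5% with the larger list of peaks, adjusted permutation p = 0.0101, in a range of 0.0101 to 0.926), 17 of 36 for tracheal and epithelial genes, 13 of 27 for dorsoventral and mesoderm genes, 6 of 16 for muscle genes, 10 of 18 for corepressor and Polycomb genes, 13 of 21 for ecdysone genes, 4 of 19 for eye genes, 3 of 16 for hemocyte genes, 4 of 17 for fat body and gut genes and 12 of 32 for proteasome genes. The lowest adjusted permutation p among these lists was 0.0994.

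**Figure D3:**
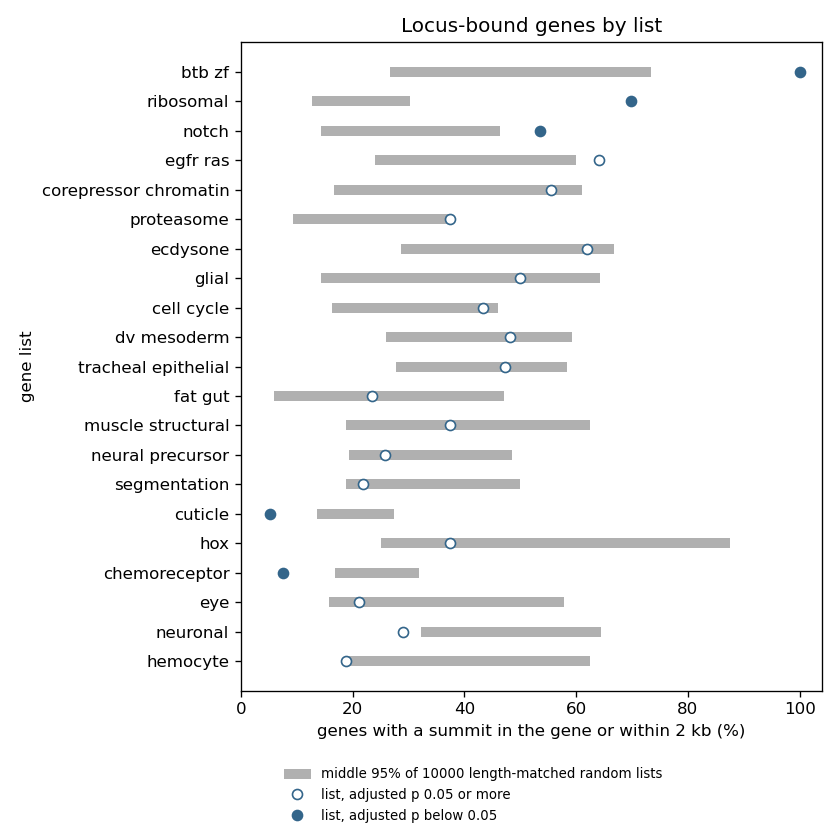
Share of genes with a summit in the gene or within 2 kb (x axis, percent) for each of the 21 gene lists (y axis); points are the lists, filled where the adjusted p was below 0.05, and grey bars span the middle 95% of 10000 length-matched random lists. BTB factor genes reach 100% and ribosomal protein genes 69.8%, while cuticle genes are at 5.13% and chemoreceptor genes at 7.56%.

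Among genes studied as tramtrack targets or as markers of the tissues it acts in, ttk itself was bound at several places. Of the 16 genes named in advance, 5 had a summit in the gene or within 2 kb, as did 28.2% of all protein-coding genes. The ttk locus (3R:31713867-31735392) held 7 summits, the strongest at -114 bp from an internal TSS (3R:31725494-31725837; signal 197, with 120 in replicate 1 and 75.8 in replicate 2). Others lay in introns (119 and 72.1), in a coding exon (95.4), upstream at -1827 bp (77.2) and beyond its end at the promoter of CstF50 (52.2 and 19, overlapping each other). The neuronal gene elav had 4 summits, led by 1 at -271 bp from its TSS (X:523374-523619; signal 527, with 324 and 199 in replicates 1 and 2). Another of the 4 elav summits, with a signal of 10.8, had no matching peak in either replicate. CycE, the G1 cyclin gene, had 1 summit at -422 bp from a TSS (2L:15746860-15747203; signal 185), and the pair-rule gene odd 1 at -35 bp (2L:3606619-3606962; signal 131). The esg locus held only weak summits 3577 bp and 3783 bp beyond its TSS (signals 68.2 and 5.71). No summit lay in or within 2 kb of eve, ftz, en, hry (hairy), stg, tll, mira, repo, sca, ase or dpn. The summit nearest to a TSS of these genes was between 5035 bp (dpn) and 34849 bp (tll) away.

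Sequence under the summits was poor in the site reported for the 69 kDa isoform of tramtrack and rich in A and T. The core AGGAC of the site of the 69 kDa isoform was found within 100 bp of 355 of 3815 summits (9.31%), against 15.8% of windows beside the same peaks (adjusted exact p = 8.33e-17). The full site GGTCCTGC was present at 3 summits (0.0786% against 0.472%, adjusted exact p = 0.00397) and its first 6 bases, GGTCCT, at 53 (1.39% against 3.72%, adjusted p = 1.13e-09). The site of the 88 kDa isoform, AGGGYGG with Y for C or T, did not differ past the threshold (2.83% against 3.28%, adjusted exact p = 0.347), and it was more frequent than in shuffled sequence of the same windows and in GC-matched flanks (1.15 and 1.07 percentage points; adjusted p = 0.00112 and 0.00501, in a range of 0.00112 to 0.837 over the alternatives). The call for the full 69 kDa site was lost with the peaks of replicate 2 alone (difference of -0.269 points, adjusted exact p = 0.123), the larger list (-0.234), the stronger part of the conservative list (-0.314), windows of 50 bp (-0.183), promoter peaks alone (-0.361), other peaks alone (-0.139) and GC-matched flanks (-0.131), in a range of 0.00589 to 0.725. GC-matched flanks also reduced the differences of AGGAC to -4.12 points and of GGTCCT to -1.28 points, from -6.50 and -2.33 (adjusted exact p = 1.7e-07 and 0.000329, with highest values over the alternatives of 0.0342 and 0.01).

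Core promoter and insulator motifs were more frequent at summits. The DRE, TATCGATA, was found at 2.36% of summits against 0.682% (adjusted exact p = 1.01e-08), the BEAF-32 core CGATA at 25.7% against 21.3%, and the M1BP motif GGTCACAC at 1.65% against 0.577% (adjusted p = 2.4e-05 for both). None of the 3 passed in peaks away from promoters, where the differences were 0, 0.279 and -0.0464 points. The windows beside the peaks were not matched on distance to a TSS. The excess of these 3 motifs therefore cannot be told apart from the position of summits at promoters. With the peaks of replicate 1 alone CGATA did not pass (2.31 points, adjusted exact p = 0.0562, in a range of 5.21e-11 to 1). The E-box CAGCTG was less frequent (8.20% against 9.83%, adjusted exact p = 0.0318), but against shuffled sequence it was 5.09 points more frequent, and with the peaks of replicate 2 alone it did not pass (-1.38 points, adjusted p = 0.123, in a range of 9.04e-22 to 0.920). The motifs of Zelda, GAGA factor, Twist, AP-1, Su(H), Pho and Grainyhead and the E-box CACGTG did not pass (adjusted exact p = 0.0666 to 0.664). Each of these but Grainyhead passed under at least 1 alternative, with lowest adjusted exact p of 1.17e-32 for GAGA factor, 0.000300 for Su(H), 0.00133 for CACGTG, 0.00175 for Zelda, 0.00269 for Twist, 0.0231 for Pho and 0.0238 for AP-1, and a highest of 1 over these motifs. With the peaks of replicate 1 alone Twist (-1.87 points) and GAGA factor (1.81) passed, and with those of replicate 2 alone CACGTG (-1.31). These calls did not all keep 1 direction. GAGA factor was 3.15 points more frequent than in GC-matched flanks (adjusted exact p = 2.93e-05), but less frequent with windows of 50 bp. Su(H), at -0.262 points in the main comparison, was more frequent than in shuffled sequence.

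Among all 6-mers, 483 were more frequent at summits and 945 less frequent than in the flanks (exact McNemar tests). Fewer were less frequent when shuffled sequence of the same windows took the place of the flanks. The 10 with the largest excess held only A and T, led by AAATAT (50.4% of summits against 28.2%; adjusted exact p = 7.7e-83), and all 36 A/T-only 6-mers were higher. Mean GC content in the central 50 bp was 34.2% ± 12.3 (SD across 3815 peaks), against 43.6% ± 12 beside the peaks. It was 30.2% in the highest of 5 equal groups by signal and 40.2% in the lowest.

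**Figure D4:**
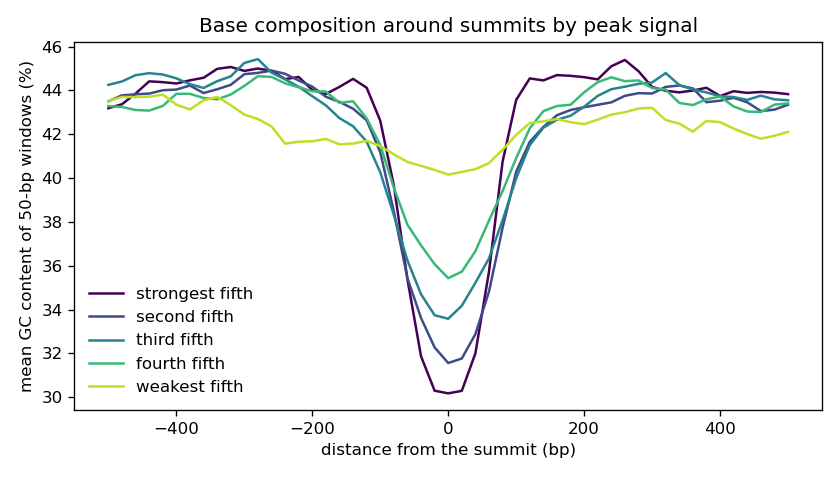
Mean GC content of 50-bp windows (y axis, percent; the axis does not start at 0) by distance from the summit (x axis, bp), with a line for each of 5 equal groups of conservative peaks by signal. At the summit the strongest group is at 30.2% and the weakest at 40.2%.

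Stronger peaks held the AGGAC core less often than weaker ones. It was present in 7.08% of peaks in the highest of the 5 signal groups and 12.7% in the lowest (Spearman rho of -0.0746 across peaks, permutation p = 1e-05, the smallest these can give; adjusted p = 4e-05). Mean GC content at the summit differed in the same way, at 30.2% in the highest group and 40.2% in the lowest. The relation was not adjusted for GC content, so it cannot tell a change in the site from a change in base composition. GGTCCTGC, GGTCCT and AGGGYGG showed no relation past the threshold (rho from -0.0249 to -0.00236, adjusted permutation p = 0.262 to 0.886). The relation of the core was lost with the peaks of replicate 1 alone (rho of -0.0298, adjusted permutation p = 0.363), and in the stronger part of the conservative list (rho of -0.0486, adjusted permutation p = 0.133), in a range of 4e-05 to 0.363 over the alternatives. With the larger list of peaks the other 3 motifs passed too, at rho of -0.0429 for GGTCCTGC, -0.0420 for GGTCCT and -0.0395 for AGGGYGG (adjusted permutation p = 0.00442, 0.00535 and 0.00702, the lowest of each over the alternatives). GGTCCTGC also passed with the peaks of replicate 2 alone (rho of -0.0419, adjusted permutation p = 0.0358).

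Transfer RNA genes, which often give nonspecific ChIP-seq peaks, were not enriched past the threshold. Within 500 bp of a tRNA gene lay 10 summits (0.262%), against 0.172% ± 0.0671 of random positions (SD of 1000 sets; permutation p = 0.266).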

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

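All tests of CACTG, and those of AGGAC within 250 bp, in the strongest peaks and against GC-matched flanks, were chosen after the result was seen.

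In the ranked list of both replicates, 92 peaks reached the score of the thresholded list and were left out of it, so the comparisons used them only in 1 alternative, chosen after seeing the data. They were not weak: the strongest, in an intron of cbt (2L:480924-481258), had a signal of 1986 and ranked 3 among all ranked peaks, and the next lay in an intron of Lk6 (3R:11760908-11761184; signal 1442). Of the 92, 51 were on 3R and 22 on 2L, and they clustered, with 5 nearest to tara (strongest signal 730), 5 nearest to Kdm2 (274), 4 nearest to Rh5 (242) and 3 nearest to cbt. Others were nearest to larp (857), trx (655), pont (619) and Alh (520). Why the 92 peaks were left out is unknown. The deposited listing names a further source, not used here, for the thresholded lists, so they may have been removed on purpose. Their high signals therefore do not show that they are binding sites.

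AGGAC, the core of the site reported for the smaller isoform of tramtrack, was scarcer at summits than beside them. The labels describe a ttk fusion and do not name the tagged isoform. The site of the larger isoform, AGGGYGG, was 1.07 points more frequent than in GC-matched flanks. Against unmatched flanks its difference was -0.446 points, which did not pass the threshold. The deficit of AGGAC therefore does not show that the tagged protein avoids its own site. Base composition does not account for the whole deficit, because the difference was -6.76 points from shuffled sequence of the same windows (9.31% against 16.1%; exact McNemar p = 4.83e-19) and -4.12 points from GC-matched flanks (13.4%), although the latter was smaller than the -6.50 points from unmatched flanks. The GC-matched flanks were themselves below shuffled sequence (13.4% against 16.1%), so part of the -6.76 points is not particular to summits. Their mean GC content was slightly above that of the summit windows (37.1% against 36.7%). A shift between summit and site is argued against by the share within 250 bp, whose difference was -8.05 points from flanks of that width (23.9% against 32.0%) and -9.17 points from GC-matched flanks. Dilution by weak peaks is argued against by the strongest of 5 signal groups, where the difference was -9.04 points from unmatched flanks, -7.60 from shuffled sequence and -3.41 from GC-matched flanks (exact McNemar p = 0.0244). In that group too the matched flanks were slightly richer in GC (35.6% against 34.8%). Binding through other proteins, or signal at open promoters that is not specific to the tagged protein, could each give such peaks and stay open, as the shuffled comparison (difference of -6.76) bears on neither and no control library was used here; no biological explanation was tested.

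In the 1000 strongest peaks, the pentamer CACTG (or its reverse complement CAGTG) flanked the summits, with 48.1% holding it 50 to 110 bp away on at least 1 side, against 17.2% in the same stretches beside the peaks and 31% in the 1000 weakest peaks; by single stretches of 60 bp, 28.8% held it on the left, 32.5% on the right and 6.90% in the centre. It was present in 45.6% of the 1000 strongest peaks of replicate 1 and 51.8% of those of replicate 2. Base composition does not account for it (27.9 points above shuffled sequence), and it is no feature of promoters alone, since in 440 peaks away from promoters the share was 43.6 points above the flanks (55.7% against 12%). GGGG exceeded CCCC by 7.70 points at the left edge and fell below it at the right edge (-8.40 points), a mirror that may come from sequence-dependent fragment ends in the libraries. Paired binding sites in opposite orientation could also give a mirror, both edges held the pentamer in 13.2% of peaks against 9.36% if independent, and neither explanation is excluded; no biological explanation was tested.

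The ttk locus held 7 summits, more than any of the 200 protein-coding genes closest in length (at most 6, median 0, percentile 100). With overlapping peaks counted once it held 6 against at most 5. Gene length does not account for the number counted this way, with 2 kb on each side of every gene. The 7 include the 2 overlapping summits at the promoter of the neighbouring gene CstF50 (signals 52.2 and 19). Without these, ttk would not exceed the highest of the other genes. An extra tagged copy of the region might raise the signal there. The 20 kb on each side held 2 summits, at percentile 58.3 of all protein-coding genes (78.1 with ties counted, 0.05 per kb against a median of 0.025). This cannot decide whether a copy reaches that far, because it counts few summits and does not measure signal. An extra copy of any extent, and binding of the protein to its own gene, both stay open. No biological explanation was tested.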

How the results depend on the processing

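The restored peaks, the minimum merged signal, counting overlapping peaks once, the GC-matched flanks, the shuffled 6-mers and the expectation from TSS numbers were chosen after seeing the data; all other alternatives were planned.

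There were 888 alternatives to 88 results. For results that answer a comparison, 268 kept the side of the threshold and, where called, the direction, which could turn in results past the threshold under neither setting. Another 20 brought a result past the threshold, 10 took one below it, 11 moved a count and 3 reversed a direction; for single lists and motifs these were 527, 27, 14, 0 and 8. The cause was not tested for any change below.

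The larger list of peaks brought past the threshold the ratios of 5' UTRs (0.602) and 3L (1.11) and the relations to signal of GGTCCTGC (-0.0429), GGTCCT (-0.0420) and AGGGYGG (-0.0395), gave 2 higher promoter lists, and ended the call of GGTCCTGC (-0.234 points). The stronger part of the conservative list brought past it 5' UTRs (0.460), introns (0.899) and 2L (1.12), and ended the calls of GGTCCTGC (-0.314 points) and of the relation of AGGAC to signal (-0.0486).

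Leaving out 1 replicate gave ratios of 0.430 to 0.726 for 5' UTRs, 0.894 to 0.972 for introns, 1.02 to 1.09 for 3L and 1.05 to 1.18 for X, 1 to 2 higher promoter lists, differences of -0.406 to -0.269 points for GGTCCTGC, and rho of -0.0804 to -0.0298 for AGGAC and -0.0419 to -0.00732 for GGTCCTGC.

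Promoters of 250 bp gave 0.669 for 5' UTRs, 1.44 for other exons and, with the direction reversed, 1.05 for introns. Promoters of 1000 bp gave 0.290 for 5' UTRs, 0.860 for introns and 2 higher lists, and whole peaks 0.474 for 5' UTRs and 1.55 for other exons. Counting neighbours once left 1 lower promoter list, and gene bodies without flanks 0 lower locus lists. TSS numbers gave 0.861 for 2R and 1.13 for 3L.

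Windows of 50 bp gave 7 lower motifs and -0.183 points for GGTCCTGC, and reversed GAGA factor (-1.47); windows of 250 bp reversed CAGCTG (0.891). Shuffled sequence gave 7 higher motifs and 573 lower 6-mers, and reversed AGGGYGG (1.15), CAGCTG (5.09) and Su(H) (1.13). Promoter peaks gave -0.361 for GGTCCTGC and reversed CAGCTG (0.241). Other peaks gave 0 higher motifs, -0.139 for GGTCCTGC, 0 for the DRE and -0.0464 for M1BP. GC-matched flanks gave 5 higher and 2 lower motifs and -0.131 for GGTCCTGC, and reversed AGGGYGG (1.07, past the threshold) and CAGCTG (0.550). Read depth is unknown, so what it limits could not be measured.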

Other observations

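The tests of head-to-head pairs and of the upstream position, and the shuffled 6-mer comparison, were chosen after the result was seen; that of the mitochondrial ribosomal protein genes was prompted by the strongest peaks, and the group's share was not known when it was chosen.

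Mitochondrial ribosomal protein genes, which no list covered, were nearest to 3 of the 25 strongest peaks, mRpL41, mRpS10 and mRpL23. Of 73 such genes, 18 had a promoter summit (24.7%, against 14.1% of all other protein-coding genes; Fisher's exact p = 0.0171). The strongest after mRpL41 (signal 1921) and mRpS10 (1496) was at mRpS23 (1391; 2L:13835321-13835624), whose promoter peak is shared with CenG1A, followed by mRpL23 (1233), mRpL20 (617) and mRpL24 (598). Without the 3 genes that prompted the test, 15 of 70 were bound (21.4%, Fisher's exact p = 0.0862), which did not pass 0.05, so the call may rest on the genes that prompted it.

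Genes in head-to-head pairs, with the TSS of another gene on the opposite strand at most 500 bp upstream, were bound at promoters more often than other genes. Of 3815 such genes (a number that equals that of the peaks by coincidence), 1049 had a promoter summit (27.5%, against 9.21% of others, Fisher's exact p = 1.82e-151). A share of 17.6% would follow if each of the 2 promoters were bound independently at the rate of the others. A single summit can count for both genes of a pair, so the p-value, which takes genes as independent, is too low. Broadly expressed genes may underlie this share of 27.5%; expression was not analysed here. Such pairs do not account for the upstream position of summits, since 83.0% of promoter summits at genes outside pairs were upstream too.

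Against dinucleotide-shuffled sequence of the same windows, 6-mers with CACTG or CAGTG stood beside A/T-rich ones at the top. ACAGTG or its reverse complement was present at 21.3% of summits against 7.60% of shuffled windows, ACACTG at 19.3% against 7.42%, CAGTGC at 18.6% against 6.76% and CAGTGG at 15.2% against 5.14%.

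The shortage of peaks on chromosome 4 extended to the ranked lists, where replicate 1 had 228 against 887 expected from length and replicate 2 had 48 against 1111. On Y replicate 1 had 28 ranked peaks against 2273 expected and replicate 2 had 460 against 2845. In the conservative list 124 peaks had a merged signal below 20. Those matched to a peak in both replicates' own ranked lists had median signals of 46.1 in replicate 1 and 40.3 in replicate 2. The match takes the nearest summit within 150 bp, which can belong to a stronger neighbouring peak. At esg the peaks with merged signals of 68.2 and 5.71 were given the same replicate 1 signal of 40.3. The replicate medians therefore do not show how well the low peaks themselves were supported.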
